A study of Homo sapiens with 12 samples.

How the data were processed

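RNA sequencing of 12 libraries was analysed from a single table of FPKM values deposited by the authors, with 54261 genes. Per the submitters' processing notes the tools HISAT2 and featureCounts and the build hg38 were used; their versions, and which step each served, are not given in the sources used here. Columns were matched to samples by the code in each sample's title, and groups came from the titles. No column was left unmatched.

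FPKM keeps the depth where whole reads were counted. For each gene a length was sought, up to 200000 bases, at which all of its values became whole reads within 1e-07 of a read, and 99.9738% of 267349 nonzero values came out whole. The recovered reads summed to at least 99.9629% of the FPKM denominator in each library, which gave depths of 11703624 to 21882537 reads. Pairs of libraries within a group differed by more than counting noise, with chi-square per degree of freedom from 1.66 to 4.07 over genes with at least 50 reads, so no library was counted as a repeat of another.

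Genes with an FPKM of at least 1 in at least 3 libraries were tested (13312). Values were log2(FPKM + 1), fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 12 libraries, and tested with empirical Bayes moderation with a variance trend. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. The 3 co-cultures were each compared with BON-1 alone and with each other, and a moderated F test covered all groups. The method was tested on simulated data for 10:6 against BON-1 alone with 13051 genes: 49.0% of genes changed 1.25-fold, 84% at 1.5-fold, 91.8% at 2-fold and 98.0% at 4-fold were recovered, and 2.45% of 163 calls were false. The simulated genes shared a single dispersion and held no GC trend, so these rates need not hold for the real comparisons.

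Before the data were examined 23 gene lists were fixed: fibroblast markers, leukocyte and endothelial markers, neuroendocrine, epithelial, mesenchymal transition, TGF-beta response, NF-kB and inflammatory, IL-6 and STAT3 response, interferon-stimulated, YAP/TEAD, WNT and NOTCH, immediate early, heat shock, DNA replication, mitotic, p53, unfolded protein and ATF4, hypoxia and glycolysis, cholesterol synthesis, nuclear oxidative phosphorylation, mitochondrially encoded, ribosomal protein and histone genes. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 23 lists of a comparison. Named genes followed a rule fixed at the same time: among protein-coding genes past the threshold with a mean FPKM of at least 5 in the higher group and no overlap between the groups' libraries, the 12 largest rises and 12 largest falls against BON-1 alone and the 5 and 5 largest between ratios, plus the 3 members of each list with the smallest p at 10:6 against BON-1 alone. Fewer were named than the rule allows.

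Alternatives fixed beforehand changed the pseudocount to 0.1, the filter, the scaling (median-of-ratios, quantile), the variance model, the libraries in the fit, the threshold (a fold of at least 2), the replicate number as a block, and left out each library in turn. Added after the data were seen were limma-voom on the recovered reads, removal of trends on gene length and GC content (for the lists also with an estimated correlation), protein-coding genes alone, and thinning of every library to the same number of reads. GC content came from the longest transcript in GENCODE 29 and gene lengths from the recovery, with both known for 12383 genes (93.02%). Gene positions were taken from GRCh38.p14. COL1A1 (Entrez gene 1277) lies on chromosome 17 from 50184101 to 50201631, SCG2 (7857) on chromosome 2 from 223596940 to 223602361, CHGA (1113) on chromosome 14 from 92922664 to 92935285, and CGA (1081) on chromosome 6 from 87085498 to 87095106. The values are sums over whole genes, so no exon was resolved. Scripts used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.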

Results

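RNA was sequenced from BON-1 cells, an established human pancreatic neuroendocrine tumour line, grown alone or sorted from co-culture with CAFs, the usual abbreviation of cancer-associated fibroblasts. The labels named 4 groups with 3 libraries each: BON-1 alone and co-cultures at BON-1 to CAF ratios of 10:2, 10:4 and 10:6. The libraries held 11703624 to 21882537 reads assigned to genes. BON-1 alone had the deepest library and the widest range, from 12918760 to 21882537, and the co-cultures lay between 11703624 and 15327524. Of 54261 genes, 13312 reached an FPKM of 1 in at least 3 libraries and were tested. Levels below are mean FPKM ± SD with n = 3, and fold changes are log2 differences of FPKM + 1, which understate the change of low genes. Nothing in the labels says that the libraries came from separate cultures. The p-values set differences against the spread within groups, which may therefore be technical. The labels do not say whether BON-1 cells grown alone went through the same sort, so comparisons with BON-1 alone can include an effect of sorting. The purity of the sort is not given either, so libraries from co-culture can include RNA of CAFs. By the moderated F test of limma, 5916 genes (44.44%) differed among the 4 groups.

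The comparison of co-culture at 10:2 with BON-1 alone asked how cells sorted from the co-culture of lowest CAF share differed. COL1A1 and COL1A2, the chains of type I collagen, went from 9.22 ± 0.148 to 18.0 ± 0.273 and from 4.08 ± 0.535 to 9.01 ± 0.436. SPARC, a matrix glycoprotein, rose from 5.05 ± 0.468 to 9.99 ± 0.0904, and ACTA2, smooth muscle actin, from 5.99 ± 0.530 to 11.04 ± 0.507 (limma adjusted p = 3.1e-06 for each of COL1A2, SPARC and ACTA2). Of 19 tested fibroblast markers, 10 rose and none fell over all genes, and 13 rose when adjusted over the list alone. The camera list test gave adjusted p = 2.22e-05, and adjusted p = 0.194 with an estimated correlation.

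Other large rises among named genes at 10:2 were in TOP2A, EPRS and SF3B1. TOP2A, the DNA topoisomerase of dividing cells, rose from 6.91 ± 0.454 to 13.1 ± 0.794. EPRS, a tRNA synthetase, rose from 10.2 ± 0.263 to 19.4 ± 0.794, and SF3B1, a splicing factor, from 18.5 ± 0.237 to 32.7 ± 0.353 (limma adjusted p = 1.17e-07). Of 30 mitotic genes, 17 rose and 2 fell, or 20 and 4 adjusted over the list alone (camera adjusted p = 0.00019, and adjusted p = 0.194 with an estimated correlation). Removal of length and GC trends took the log2 rise from 0.84 to 0.52 for TOP2A and from 0.79 to 0.51 for SF3B1, and left 9 mitotic genes rising and 2 falling, with the list median going from 0.213 to 0.0572. The mitotic genes had a median GC content of 42.55%, against 49.75% over all genes with a value. Of protein-coding genes under the naming rule, the 12 with the largest falls at 10:2 changed less than the 12 with the largest rises; over all genes 12 rose and 8 fell at least 2-fold, of which 2 and 0 were protein-coding. NR4A1, an immediate early transcription factor, fell by 0.39 on the log2 scale. Of 20 immediate early genes, 9 fell and 1 rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000142, and adjusted p = 0.194 with an estimated correlation). Of 26 ribosomal protein genes, 6 fell and 2 rose under both adjustments (camera adjusted p = 0.0295, and adjusted p = 0.719 with an estimated correlation). Both calls ended when length and GC trends were removed, where 2 immediate early genes fell and 0 rose (adjusted p = 0.0742) and 7 ribosomal protein genes fell and 1 rose (adjusted p = 0.105). In all, 3648 genes changed, 2655 up and 993 down. After removal of trends on gene length and GC content the count was 1429, with 52.06% rising in place of 72.78%.

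**Figure D1:**
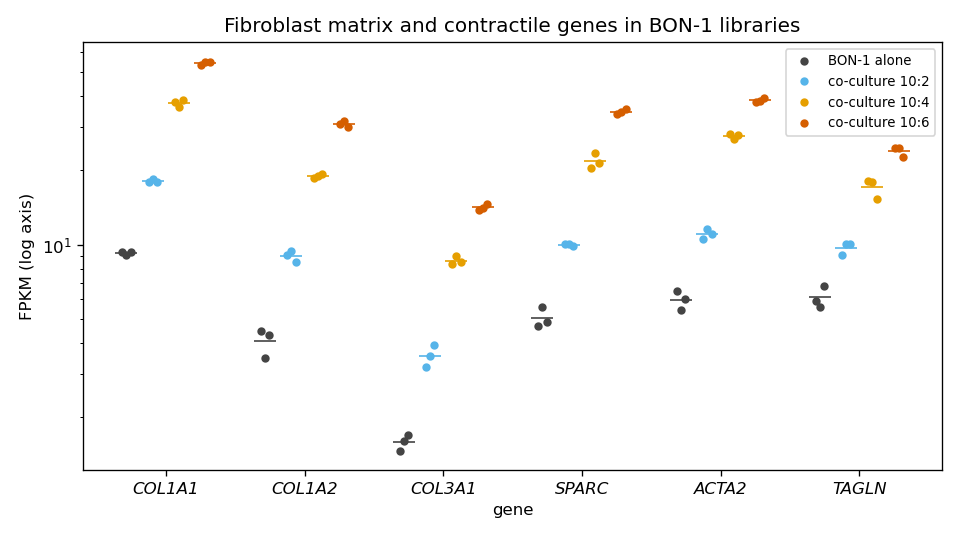
FPKM on a log axis of 6 fibroblast genes in each library, with points for the 3 libraries of a group and a dash for the group mean. The mean of COL1A1 climbed from 9.22 in BON-1 alone to 18.0, 37.4 and 54.4 at ratios of 10:2, 10:4 and 10:6.

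Co-culture at 10:4 was compared with BON-1 alone to ask the same of an intermediate CAF share. ACTA2 reached 27.6 ± 0.613, a rise of 2.03 ± 0.0535 (SE) on the log2 scale, and COL3A1, the type III collagen chain, rose from 1.59 ± 0.113 to 8.59 ± 0.332. IGFBP7, a secreted growth factor binding protein, rose from 2.88 ± 0.223 to 11 ± 1.19. Of 19 fibroblast markers, 15 rose and none fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 9.05e-09, and adjusted p = 0.0518 with an estimated correlation). TOP2A reached 19.3 ± 1.32, a log2 rise of 1.36, or 0.90 with length and GC trends removed. Of 30 mitotic genes, 22 rose and 3 fell, or 22 and 4 adjusted over the list alone (camera adjusted p = 5.96e-05, and adjusted p = 0.221 with an estimated correlation), and with the trends removed 14 rose and 3 fell. Of 20 immediate early genes, 13 fell and 1 rose under both adjustments (camera adjusted p = 0.000577, and adjusted p = 0.221 with an estimated correlation). That call ended when length and GC trends were removed, where 6 fell and 1 rose (adjusted p = 0.0791).

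The largest fall at 10:4 among protein-coding genes under the naming rule was in TTR, the thyroid hormone carrier transthyretin, from 6.38 ± 0.953 to 3.32 ± 0.817. IHH, a hedgehog ligand, fell from 48.1 ± 0.263 to 34.4 ± 0.556, and WNT7B, a WNT ligand, from 15.7 ± 0.325 to 11.9 ± 0.663. CGA, the common alpha subunit of the glycoprotein hormones, had 42.6 ± 36.3 in BON-1 alone and 134.6 ± 12.4 at 10:4 (limma adjusted p = 0.0133), and without BON-1 alone replicate 1 the adjusted p was 0.0566. CGB3, CGB5 and CGB8, near-identical beta subunit genes among which reads cannot be assigned with certainty, were also called. The call for CGB5 ended without BON-1 alone replicate 1 (adjusted p = 0.118) or 3 (0.0598) or 10:4 replicate 2 (0.0745) or 3 (0.073), without the filter on low values (0.0924) and with a robust variance model (0.0651). In all, 6046 genes changed, 3638 up and 2408 down. With length and GC trends removed the count was 2890, of which 45.74% rose in place of 60.17%, and among genes with a mean FPKM of at least 5 the share was 44.68%.

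**Figure D2:**
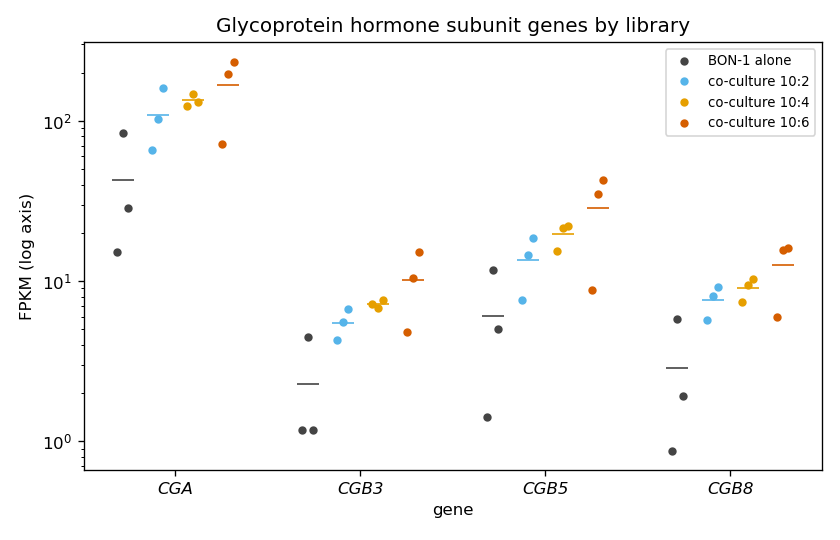
FPKM on a log axis of the glycoprotein hormone subunit genes in each library, with points for the 3 libraries of a group and a dash for the group mean. Libraries of BON-1 alone ran from 15.2 to 83.8 for CGA and those of 10:6 from 71.8 to 233.8.

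Co-culture at 10:6 was compared with BON-1 alone to ask the same of the highest CAF share. COL1A1 reached 54.4 ± 0.794, COL1A2 30.8 ± 0.802, SPARC 34.6 ± 0.726, ACTA2 38.5 ± 0.723 and COL3A1 14.2 ± 0.438, with log2 rises from 2.44 to 2.65. TAGLN, an actin-binding protein of contractile cells, rose from 6.12 ± 0.622 to 24.0 ± 1.10, and MYL9, a myosin light chain, from 1.75 ± 0.0856 to 7.93 ± 0.357. Of 19 fibroblast markers, 16 rose and 1 fell under both adjustments (camera adjusted p = 1.74e-10, and adjusted p = 0.0301 with an estimated correlation). Of 5 tested leukocyte and endothelial markers, 2 rose and 1 fell under both adjustments (camera adjusted p = 0.861), or 1 and 0 with length and GC trends removed.

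Granins, proteins of the secretory granules of neuroendocrine cells, moved apart. SCG2 rose from 746.7 ± 5.35 to 1401 ± 7.84, a log2 change of 0.91 ± 0.0294 (SE, limma adjusted p = 4.16e-09), and CHGB rose from 218.7 ± 2.82 to 274.1 ± 8.34. CHGA fell from 1347 ± 25.9 to 975.1 ± 39.2 (limma adjusted p = 6.65e-07). With length and GC trends removed the log2 changes were 0.60 for SCG2, 0.40 for CHGB and −0.33 for CHGA. Of 20 neuroendocrine genes, 8 rose and 7 fell under both adjustments, or 4 and 5 with the trends removed, and the list as a whole did not pass (camera adjusted p = 0.849).

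**Figure D3:**
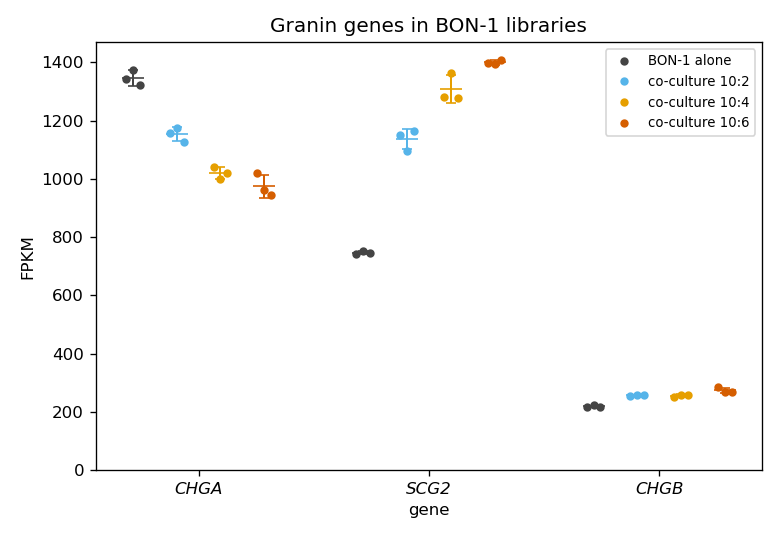
FPKM of CHGA, SCG2 and CHGB in each library, with points for the 3 libraries of a group, dashes for means and bars for the SD. CHGA fell from 1347 to 975.1 between BON-1 alone and 10:6 while SCG2 rose from 746.7 to 1401.

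Epithelial genes went both ways at 10:6. DSP, desmoplakin, rose from 16.1 ± 0.131 to 27.2 ± 0.681, and EPCAM from 303.2 ± 3.02 to 368.4 ± 9.47. Of 18 epithelial genes, 8 rose and 5 fell, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.849). When the trends were removed the log2 rise of EPCAM went from 0.28 to 0.17, 4 genes rose and 1 fell, and the list passed (adjusted p = 0.00448, and adjusted p = 0.0356 with an estimated correlation). The chaperonin HSPD1 rose from 257.6 ± 5.61 to 433.9 ± 19.7, and 8 of 15 heat shock genes rose with 4 falling under both adjustments (camera adjusted p = 0.144). With the trends removed the log2 rise of HSPD1 went from 0.75 to 0.50, and 7 rose and 3 fell (adjusted p = 0.0141, and adjusted p = 0.175 with an estimated correlation). Of 30 mitotic genes, 20 rose and 4 fell under both adjustments, with BUB1, a spindle checkpoint kinase, at 16.4 ± 0.547 and 27.7 ± 0.146 (camera adjusted p = 0.00527, and adjusted p = 0.325 with an estimated correlation). After removal of the trends that call ended (adjusted p = 0.136) with 9 rising and 6 falling, and the log2 rise of BUB1 went from 0.72 to 0.38. TOP2A was at 14.7 ± 0.705, below its mean of 19.3 at 10:4. Its log2 rise over BON-1 alone was 0.99, or 0.56 with the trends removed. REG4, a secreted lectin, fell from 11.03 ± 1.13 to 7.68 ± 0.994, and WNT7B fell to 10.6 ± 0.311.

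The other lists fixed before the data were examined did not pass at 10:6. Members that rose and fell were 8 and 0 of 13 mesenchymal transition genes, 7 and 2 of 17 TGF-beta response genes, 3 and 2 of 11 NF-kB and inflammatory genes, 4 and 1 of 14 IL-6 and STAT3 response genes, and 7 and 0 of 23 interferon-stimulated genes. They were 8 and 1 of 18 YAP/TEAD targets, 2 and 1 of 15 WNT and NOTCH targets, 3 and 8 of 20 immediate early genes, 12 and 12 of 30 DNA replication genes, 8 and 3 of 19 p53 targets, and 13 and 7 of 28 unfolded protein and ATF4 response genes. They were 5 and 11 of 27 hypoxia and glycolysis genes, 9 and 12 of 23 cholesterol synthesis genes, 5 and 13 of 26 nuclear oxidative phosphorylation genes, 2 and 7 of 15 mitochondrially encoded RNAs, 3 and 11 of 26 ribosomal protein genes, and 1 and 2 of 17 histone genes. Adjusted over the list alone, the counts were 8 and 1 for mesenchymal transition, 8 and 2 for TGF-beta response, 3 and 4 for NF-kB, 6 and 0 for interferon-stimulated, 9 and 1 for YAP/TEAD, 14 and 8 for unfolded protein, 4 and 12 for ribosomal protein and 0 and 0 for histone genes, and were the same for the remaining lists. With length and GC trends removed the mesenchymal transition, TGF-beta response and interferon-stimulated lists passed with either correlation (adjusted p = 0.0291, 0.0195 and 0.0291 with an estimated one), and the oxidative phosphorylation and ribosomal protein lists with the preset one only. Members that then rose and fell were 4 and 1 for YAP/TEAD, 2 and 8 for DNA replication, 3 and 2 for p53, 6 and 5 for unfolded protein, 2 and 8 for cholesterol synthesis, 3 and 8 for hypoxia and glycolysis, 2 and 2 for NF-kB, 3 and 0 for IL-6 and STAT3, 3 and 2 for WNT and NOTCH and 1 and 3 for histone genes, and for immediate early genes the excess of falls turned to 5 rising and 2 falling. Without trend removal, mesenchymal transition and TGF-beta genes that rose at 10:6 had medians of 0.139 and 0.146 of that rise at 10:2. These are shares in FPKM, and the median was 0.181 for the fibroblast markers. Median, mean and test differed in sign for the NF-kB, WNT and NOTCH, DNA replication, p53 and cholesterol lists. In all, 6394 genes changed at 10:6, 3953 up and 2441 down. With length and GC trends removed the count was 3165, of which 44.96% rose in place of 61.82%, and among genes with a mean FPKM of at least 5 the share was 47.19%.

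Fold changes followed the GC content of the transcripts in the 3 comparisons with BON-1 alone and in those of 10:4 and 10:6 with 10:2. Across 12383 genes, which are not independent replicates, Spearman's rho between GC content and log2 fold change was −0.677 at 10:2, −0.716 at 10:4 and −0.720 at 10:6. Between ratios it was −0.501 for 10:4 against 10:2, −0.476 for 10:6 against 10:2 and 0.00712 for 10:6 against 10:4. In the fifth of genes with the lowest GC content 77.7% rose at 10:6 and 0.283% fell, and in the fifth with the highest 1.37% rose and 44.1% fell.

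**Figure D4:**
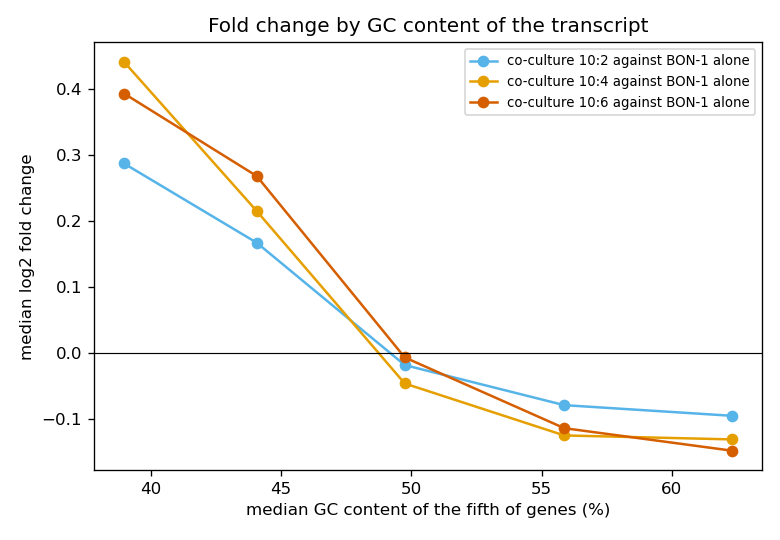
Median log2 fold change against BON-1 alone (vertical axis) of genes in 5 equal classes of GC content (horizontal axis, median percent), for 3 co-culture ratios. At 10:6 the median went from 0.393 in the class of lowest GC content to −0.148 in the class of highest.

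The co-culture ratios were compared with each other to ask what more CAFs added. From 10:2 to 10:4, ACTA2 rose by 1.247 ± 0.0535 (SE) on the log2 scale and COL1A1 by 1.01 ± 0.0339. From 10:4 to 10:6, COL1A2 rose by 0.67 ± 0.0672 and COL3A1 by 0.66 ± 0.0631, while RANBP2, a nuclear pore protein, fell from 13.2 ± 1.31 to 8.37 ± 0.381 and KIF5B, a kinesin motor, from 17.6 ± 0.741 to 11.97 ± 1.13. Both falls were not called in a fit of those groups alone (RANBP2 adjusted p = 0.0557, KIF5B adjusted p = 0.0687). From 10:2 to 10:6, COL3A1 rose by 1.74 ± 0.0631 and CRYM, a thyroid hormone binding protein, fell from 8.39 ± 0.585 to 6.14 ± 0.284. The call for CRYM ended without 10:2 replicate 2 (adjusted p = 0.0682), 10:6 replicate 2 (0.0661) or 10:6 replicate 3 (0.058). Fibroblast markers rose in 12, 7 and 14 of 19 cases for 10:4 against 10:2, 10:6 against 10:4 and 10:6 against 10:2, and in 15, 13 and 17 adjusted over the list alone. The camera test passed each time with an estimated correlation as well (adjusted p = 0.00305, 0.00401 and 0.00124).

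Without trend removal, other lists passed between ratios with the preset correlation only. For 10:6 against 10:2, 5 of 13 mesenchymal transition genes and 5 of 17 TGF-beta response genes rose with none falling, or 5 and 7 with 0 and 1 falling adjusted over the list alone (camera adjusted p = 0.00142 for each, and adjusted p = 0.0507 for each with an estimated correlation). Fibroblast markers rose in the same comparison, 14 of 19. TGFBI, a matrix protein that belongs to both lists, was 51.6 FPKM at 10:2 and 70.4 FPKM at 10:6. For 10:6 against 10:4, 3 of 30 mitotic genes fell and none rose, or 9 fell adjusted over the list alone (camera adjusted p = 5.12e-05, and adjusted p = 0.125 with an estimated correlation). With the preset correlation 3, 8 and 7 of 23 lists passed for 10:4 against 10:2, 10:6 against 10:4 and 10:6 against 10:2, and with an estimated correlation 1 each, the fibroblast markers. Changed genes numbered 384 for 10:4 against 10:2 (329 up, 55 down), 44 for 10:6 against 10:4 (13 up, 31 down) and 928 for 10:6 against 10:2 (602 up, 326 down). Leaving out single libraries gave 45 to 461, 12 to 42 and 229 to 1105. The excess of falls at 10:6 against 10:4 turned without 10:4 replicate 2 (9 up, 3 down), 10:4 replicate 3 (8 and 6), 10:6 replicate 1 (8 and 4) or 10:6 replicate 2 (10 and 9), without the filter on low values (9 and 7) and in a fit of those groups alone (7 and 5). The excess of rises at 10:6 against 10:2 turned with median-of-ratios rescaling (455 up, 482 down) and with length and GC trends removed (206 up, 241 down). In the order above, limma-voom gave 1044, 276 and 1541 genes, trend removal 118, 94 and 447, no filter 179, 16 and 477, and a fit of the groups compared alone 48, 12 and 263, and protein-coding genes alone gave 717 and 109 for the first and second.

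Most calls at 10:2 were also made at the higher ratios, and most falls called at the higher ratios were not called at 10:2. A missing call is not a difference. At 10:6, 2441 genes fell against BON-1 alone, and 326 fell in the direct test against 10:2. Of the genes that rose at 10:2, 2570 (96.8%) also rose at 10:6, where independent lists would share 788.4, and 777 (78.2%) of those that fell also fell, where independent lists would share 182.1. The shared genes were 65.0% of the rises and 31.8% of the falls at 10:6, and those shared by 10:2 and 10:4 were 70.0% of the rises and 32.9% of the falls at 10:4. The rises and falls shared by 10:4 and 10:6 were 84.7% and 72.4% of those at 10:6. Across genes the fold changes at 10:2 and 10:6 correlated with r = 0.785, against 0.494 in simulated unchanged groups sharing the same controls. Their covariance was 0.0560 against 0.00784 simulated. For 10:4 and 10:6 the covariance was 0.0813 against 0.00793, and for 10:2 and 10:4 it was 0.0592 against 0.00789. Noise of the shared controls at the fitted spread was part of the simulation. The 3 control libraries cannot be split into parts of at least 2 libraries, so a departure common to these controls may still give part of the excess. The simulation held no trend on GC content, which the fold changes against BON-1 alone followed. That trend may also account for part of the excess and of the shared calls.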

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

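BTG2, an antiproliferative immediate early gene, was called in opposite directions at different CAF shares. It averaged 34.73 FPKM in BON-1 alone, 32.31 at 10:2, 32.48 at 10:4 and 39.48 ± 0.549 (SD, n = 3) at 10:6. The differences between ratios were themselves called by limma: 0.274 on the log2 scale for 10:6 against 10:4 (adjusted p = 0.00567) and 0.282 for 10:6 against 10:2 (adjusted p = 0.00151). With length and GC trends removed the falls against BON-1 alone were not called (−0.0697 at 10:2, adjusted p = 0.181, and −0.0344 at 10:4, adjusted p = 0.481), and the rise at 10:6 was (0.199, adjusted p = 0.000716). Groups of 3 libraries were not tested for outlying samples.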

How the results depend on the processing

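Limma-voom, trend removal (also with an estimated correlation), the restriction to protein-coding genes and thinning were chosen after the data were seen. Counts against BON-1 alone stayed within 1.5 times of 3648, 6046 and 6394 except under a fold of at least 2 (20, 81 and 51) and removal of length and GC trends (1429, 2890 and 3165, with 52.06%, 45.74% and 44.96% rising; 2885 in place of 5916 for the F test). Quantile normalization changed the rising share to 61.89%, 43.75% and 44.88% from 72.78%, 60.17% and 61.82%, and median-of-ratios rescaling changed it to 48.56% from 64.87% for 10:6 against 10:2, where quantile normalization gave 52.06%; for 10:4 against 10:2 quantile normalization gave 75.68% in place of 85.68%. Restriction to a mean FPKM of at least 5 gave 59.55%, 44.68% and 47.19% rising against BON-1 alone. In the order 10:4 against 10:2, 10:6 against 10:4 and 10:6 against 10:2, in place of 384, 44 and 928, no filter gave 179, 16 and 477; only the groups compared 48, 12 and 263; a fold of at least 2 gave 13, 1 and 28; limma-voom 1044, 276 and 1541; trend removal 118, 94 and 447, with 68.64%, 32.98% and 46.09% rising. Protein-coding genes alone gave 717 and 109 for the first and second, quantile normalization 69 and thinning 18 for the second, and a variance model without trend 584 for the third. Of the list tests 27 passed, 46 with no filter, 4 with an estimated correlation, 38 with trends removed and 18 with both. The causes were not tested, except that a fold limit leaves fewer calls by construction.

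Leaving out a library gave 45 to 461, 12 to 42 and 229 to 1105 for the same order. For 10:4 against 10:2 the count fell beyond 1.5 times without BON-1 alone replicates 1 (244) and 2 (250), 10:2 replicates 1 (201), 2 (60) and 3 (230), and 10:4 replicate 2 (45). For 10:6 against 10:2 it did so without 10:2 replicates 1 (597), 2 (252) and 3 (600) and 10:6 replicates 2 (338) and 3 (229). For 10:6 against 10:4 it did so without any library but 10:2 replicate 2 (42) and 10:4 replicate 1 (39). Its 13 rises and 31 falls became 9 and 7 with no filter, 7 and 5 with only the groups compared, 1 and 0 under a fold of at least 2, and 9 and 3, 8 and 6, 8 and 4 and 10 and 9 without 10:4 replicates 2 and 3 and 10:6 replicates 1 and 2.

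The replicate number as a block gave 175, 15 (8 rises and 7 falls) and 542 for the same order, and did not move the other counts beyond 1.5 times. The numbers did not pair the libraries: the 18 pairs with the same number correlated at −0.0427 to 0.0458, and 2 of 12 libraries correlated best with their own number.

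Of 1924 list tests under the alternatives 1820 kept their side of the threshold, 36 lost the call and 68 gained it. Of 4124 values of named genes 3870 kept both, 250 were no longer past the threshold, and 4 changed sign. The sign changes were all under trend removal at 10:6 against BON-1 alone. RPL5 (−0.118, limma adjusted p = 0.0041) and RPS6 (−0.0711, limma adjusted p = 0.0189) were called in the new direction. SOD2 (−0.117, limma adjusted p = 0.0614) and HIST1H2BK (0.0258, limma adjusted p = 0.712) were no longer called. The cause was not tested. The count test planned for a table of counts was not run, since the table holds FPKM. Depth ran from 11703624 to 21882537 reads.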

Other observations

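The tests on fibroblast markers and on shares of a rise, the tests of carried CAF RNA and of depth for mitotic genes, and the tests of counting noise and paralogs for CGA, and the use of trend removal and thinning, were chosen after the results were seen. After removal of length and GC trends, lists passed camera that the untreated values had not. The first adjusted p is with the preset correlation and the second with an estimated one. At 10:6, 10 of 17 TGF-beta response genes rose and 2 fell (0.000222 and 0.0195), 6 and 0 of 13 mesenchymal transition genes (0.00207 and 0.0291), 9 and 0 of 23 interferon-stimulated genes (0.00262 and 0.0291) and 4 and 1 of 18 epithelial genes (0.00448 and 0.0356). Of 26 nuclear oxidative phosphorylation genes 2 rose and 12 fell (0.00262 and 0.176), and of 26 ribosomal protein genes 1 and 11 (0.0135 and 0.474). At 10:4 the mesenchymal transition (0.00668 and 0.0662), TGF-beta response (0.0177 and 0.0808) and oxidative phosphorylation lists (0.0303 and 0.435) passed with the preset correlation only. Heat shock genes likewise passed at 10:2, 10:4 and 10:6 (0.00208, 0.00172 and 0.0141, against 0.171, 0.0997 and 0.175 estimated). Shares of a rise were taken from FPKM without trend removal, over the genes that were called to rise there. The mesenchymal transition and TGF-beta genes that so rose at 10:6 were not on the fibroblast list. At 10:2 they had a median of 0.139 (8 genes, 0.0511 to 1.03) and 0.146 (7 genes, −0.0975 to 0.777) of that rise. These medians were near the 0.181 of the fibroblast markers, so the list calls do not tell a change in BON-1 cells from carried CAF RNA. The median was 0.383 for interferon-stimulated and 0.537 for epithelial genes. Fibroblast markers, which without trend removal passed with an estimated correlation only at 10:6 among the comparisons with BON-1 alone, then passed with it at each ratio (0.00182, 0.000218 and 0.000115).

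Fibroblast markers rose with the CAF share of the culture. Rescaling between libraries left a median log2 rise of 1.19 at 10:6, which argues against scaling. The 16 markers that rose reached a median of 0.181 of their 10:6 rise at 10:2 (SD 0.103, from −0.0389 to 0.455 across markers) and 0.622 at 10:4. The 3937 other genes that rose had a median of 0.647 at 10:2, and 0 of 10000 random lists of 16 of them lay as low. Those lists took genes as independent and came from rises that include the GC trend, so their count gives no chance level. Low medians were not particular to the markers: mesenchymal transition and TGF-beta genes had 0.139 and 0.146, and mitotic genes 0.752. RNA of CAFs carried through the sort is a candidate explanation that this test left standing. The test set no lower limit on the share at 10:2. A share in step with the CAF parts would be 2 of 6 at 10:2 and 4 of 6 at 10:4. The median at 10:2 lay below that and the median at 10:4 near it, so carried RNA in simple proportion does not describe both. The sources used here do not give the purity of the sort, so whether it removed all CAFs is not known. Expression of these genes by BON-1 cells stays open, since 12 of these 16 (15 of the 28 listed markers) exceeded 1 FPKM in each BON-1 alone library and bulk values give no level per cell.

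Of 30 mitotic genes 17, 22 and 20 rose and 2, 3 and 4 fell at 10:2, 10:4 and 10:6, and with an estimated correlation the list test did not pass (adjusted p = 0.194, 0.221 and 0.325). The median log2 level of the list spanned 0.00603 over the BON-1 alone libraries, which differed 1.69-fold in depth, more than the group means of BON-1 alone and 10:4 (1.29-fold), which argues against depth; thinning keeps the expected FPKM and decides nothing (0.400). A median of 0.752 of the 10:6 rise was already reached at 10:2, which argues against carried CAF RNA as the main source. The median was 0.647 for all genes that rose apart from the fibroblast markers. These rises include the GC trend, so a smaller part from CAFs is not excluded. Removal of length and GC trends took the list median at 10:4 from 0.411 to 0.0889 (interquartile range 0.458). That lay within the bound for a trend as the cause, set before the removal but with the untreated median known. After removal 14 of 30 genes still rose and 3 fell. The camera list test passed at 10:2 and 10:4 with the preset correlation but not with an estimated one (adjusted p = 0.171 and 0.0662). At 10:6 it passed with neither. A GC trend may account for much of the shift, and whether it accounts for all of it stays open. Whether that trend arose in library preparation or in the cells stays open, since all BON-1 alone libraries lay on 1 side of it.

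CGA and CGB genes differed several-fold between libraries of the same group, with a range in CGA of 5.51-fold in BON-1 alone, 2.44-fold at 10:2 and 3.26-fold at 10:6 but 1.19-fold at 10:4. Chi-square per degree of freedom of CGA reads was at least 12.7 in each group, which argues against counting noise. Deviations from group means of CGA and the summed CGB genes correlated over 12 libraries (r = 0.984, Spearman's rho = 0.951, permutation p = 0.0015 for r, and r = 0.967 without the 2 farthest libraries), which argues against reads shared between CGB paralogs. Syncytiotrophoblast genes summed to 10.2% of the CGA level in the library with most CGA, just past the 10% set beforehand for placental RNA. By its own rule that explanation was not set aside, but the bound was a poor one. KISS1 and ADAM12 gave 5.86 and 9.55 FPKM of that sum and averaged 8.53 and 9.88 FPKM in BON-1 alone. CSH1 was listed at 0, and leaving out KISS1, a choice made after its level was seen, gave 7.74%. The 18 genes summed to 23.9 FPKM in the library with most CGA (233.8 FPKM) and to 23.4 FPKM in that with least (15.2 FPKM). This comparison of sums was not part of the rule set beforehand. It cannot decide on placental RNA, since KISS1 and ADAM12, which BON-1 cells grown alone also expressed, weigh heavily in both sums. Among the other genes some were higher and some lower in the library with most CGA than in BON-1 alone, so placental RNA stays open. The remaining libraries were not compared in this way.

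Chance was weighed by other splits of the libraries. For the F test 1 of 100 splits, the real one, gave as many as 5916 genes, and the highest other gave 3390. A random assignment of these libraries to the groups can be excluded there. Since the labels do not show separate cultures, a difference between cultures or preparations cannot. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05, and the real split was 1 of them. The real and highest other counts were 3648 and 1 for 10:2, 6046 and 2 for 10:4 and 6394 and 0 for 10:6 against BON-1 alone, 384 and 2 for 10:4 against 10:2, 44 and 1 for 10:6 against 10:4, and 928 and 0 for 10:6 against 10:2.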
